A study of Mus musculus with 8 samples.

How the data were processed

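Total RNA from the ductus arteriosus and the aorta of fetal mice was hybridised to Affymetrix mouse arrays, 1 array per pool and 4 arrays per tissue. Per the series' design text, a pool held the vessel segments of up to 10 pups from a single pregnant female, collected on day 19 of gestation. The replicates are labelled as biological, so the p-values measure the spread between litter pools. The deposited values are on the log2 scale, and the submitters' processing notes name Partek 6.6 and RMA (robust multi-array averaging: background correction, quantile normalization and a summary of each probe set). The order and settings of these steps are not given in the sources used here. The values ran from 1.74 to 13.87, with no missing value. Array medians lay between 4.36 and 4.42 and first quartiles between 2.74 and 2.86. The tables used hold no detection call, so a fold against a level near the first quartile can be compressed. The number of arrays limits the precision.

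The table held 45101 probe sets. Control probe sets (64) were left out, 9160 were not listed in the annotation used and stayed unnamed here, 932 carried several gene symbols and 34945 carried exactly 1. Of the last, 34741 were matched to the reference gene table by gene ID and 204 kept the platform's symbol. Each of 18193 genes was represented by the probe set with the highest mean over the 8 arrays. Several probe sets existed for 9010 genes. No low-value filter was applied.

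Differences between the tissues, ductus minus aorta, were tested gene by gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior, two-sided, no covariate). All p-values of single genes below are limma's, adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p under 0.05. Counts with an absolute log2 difference of at least 1 (2-fold) are also given. Errors of differences are the model's standard errors, and those of levels are standard deviations over 4 arrays. The 37 gene lists were fixed before the data were examined, from textbook knowledge of the vessel wall and of neighbouring tissues. Those with at least 5 measured members, 36 lists, were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists. The list of sex-linked genes had 4 measured members and was not tested. Camera with an estimated correlation and fry were alternatives.

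The genes named were chosen by a rule set before the data were examined. It took the 12 genes with the largest difference in each direction among called genes without overlap between the tissues, leaving out model or clone names and sex-linked genes. It also took a fixed set of anchor genes, known from earlier ductus work or basic to the vessel wall, and up to 4 members per list with the smallest adjusted p under 0.05 (up to 2 with the largest difference where none passed). The text does not print each of them. Tbx20, Sftpc, Myh3 and Ucp1 were chosen after their values were seen. The 22 anchor genes named in the annotation used are reported.

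On simulated arrays built from the 18193 genes' means and variances with 200 changed genes, 89% of genes changed by log2 1 and 100% of those changed by log2 2 were recovered, with 7 false calls among 196. In a second simulation a single shifted list was called and 0 of the other lists were. Both simulations drew each gene independently, so they cannot show false list calls that come from correlated members.

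Alternatives covered the scaling of the arrays, filters on low values, the choice of probe set, the variance prior, array weights, a replicate block, the threshold and test, and leaving out each array. Covariates for thymus, skeletal muscle and adipocyte genes were added after seeing the data. Autosomal genes were picked by the chromosome in the reference gene table.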

Results

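The ductus arteriosus is the fetal vessel that carries blood from the pulmonary artery to the descending aorta and closes after birth. Its transcripts were compared with those of the aorta in fetal mice on day 19 of gestation, on 4 arrays of pooled ductus and 4 of pooled aorta. Correlations over all genes were 0.986 to 0.992 between arrays of the same tissue and 0.979 to 0.987 between tissues. The first principal component held 36.8% of the variance and separated the tissues, with scores of 24.6 to 29.0 for the ductus and -29.9 to -19.7 for the aorta.

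In the group counts, 10 of 26 Hox genes, 6 of 24 contractile smooth muscle genes and both genes of the vascular ATP-sensitive potassium channel were higher in the ductus, while 8 of 10 mesothelial and 4 of 23 endothelial markers were higher in the aorta. Of 18193 genes, 328 were higher in the ductus and 374 in the aorta, 186 and 202 of them at least 2-fold. Tfap2b, an AP-2 transcription factor whose loss in humans and mice leaves the ductus open, was 33.1-fold higher in the ductus, at 7.59 ± 0.093 against 2.54 ± 0.277 (log2 mean ± SD, n = 4 each; adjusted p = 2.40e-07). This aorta mean lies below the first quartile of every array (2.74 to 2.86) and is not shown to be above background, so the fold and its rank are not exact. The called genes largely did not overlap between tissues: 698 of the 702 had every ductus value on one side of every aorta value, as did 11.3% of all genes tested, against 2.86% by chance. The call itself favours genes without overlap, so the 698 are no separate support. The count moved by over 1.5 times on leaving out aorta replicate 2 (443 genes) or ductus replicate 4 (454 genes), and the count higher in the aorta also without ductus replicate 1 (239) or ductus replicate 2 (230).

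**Figure D1:**
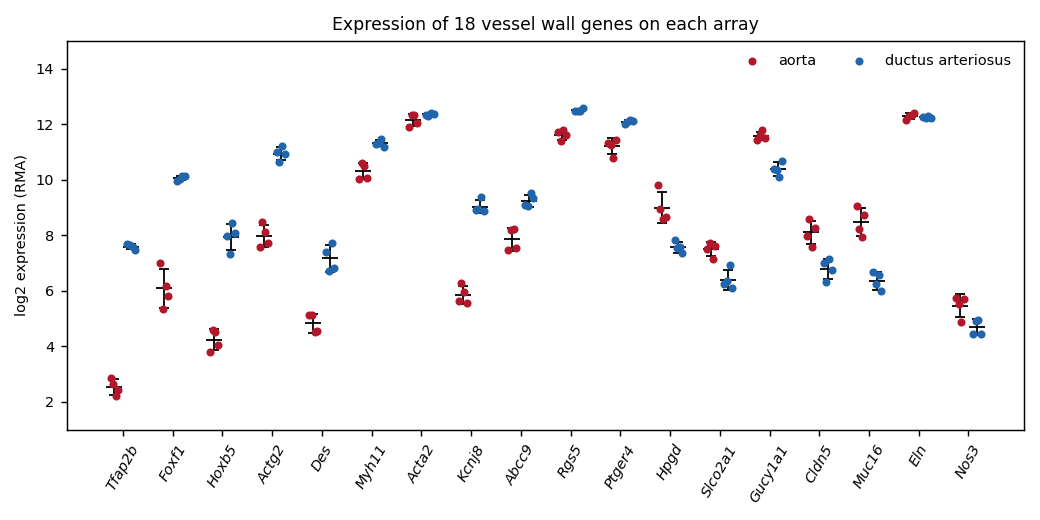
Log2 expression (vertical axis, RMA values) of 18 vessel wall genes on each of the 4 aorta arrays (red) and 4 ductus arrays (blue). Points are arrays and bars the mean ± SD; Tfap2b averaged 2.54 in the aorta and 7.59 in the ductus, while Eln (12.3 in both) did not separate the tissues.

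Besides Tfap2b, the largest differences in favour of the ductus were in Cxcl15, a chemokine of lung epithelium (35.4-fold, adjusted p = 1.15e-05), Hoxb5os, an antisense transcript of the Hoxb cluster (28.9-fold, adjusted p = 2.40e-07), and Dcc, the netrin receptor (22.3-fold, adjusted p = 1.15e-05). The kainate receptor subunit Grik2 was 18.7-fold higher, the AMPA receptor-associated Shisa9 18.04-fold, the POU factor Pou4f1 14.6-fold and the presynaptic scaffold Rims2 12.4-fold. The forkhead factor Foxf1 was 15.7-fold, Hoxb5 13.1-fold, the BMP antagonist Grem1 12.3-fold and Nell1 11.4-fold higher. Adjusted p-values of these genes were between 1.93e-06 and 0.00303. Not all probe sets went in this direction for Dcc (2 of 3), Rims2 (3 of 5) and Nell1 (1 of 2). The aorta means of Hoxb5os (2.68), Grik2 (2.62) and Rims2 (2.53) were also below every first quartile, so their folds and ranks are not exact either. Those of Dcc (2.99) and Grem1 (3.27) lay little above the first quartiles, so these folds can be compressed too.

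In the aorta, the cystatin Cst9 was higher by a log2 difference of -4.06 ± 0.374 (SE; 16.7-fold, adjusted p = 0.000388). Secreted peptides followed: Calcb, a calcitonin gene-related peptide, was 9.46-fold, Apela, a ligand of the apelin receptor, 9.04-fold, Slurp1 8.22-fold and Grp, gastrin-releasing peptide, 6.96-fold higher in the aorta. The calcium channel subunit Cacna2d3 was 6.17-fold, Clic3 5.20-fold, the natriuretic peptide convertase Corin 5.15-fold, Pard6b 5.03-fold, Fgfbp1 4.92-fold and the keratin Krt7 4.91-fold higher. The ductus mean of Cacna2d3, 2.39, was below every first quartile. Adjusted p-values of these genes were between 1.91e-05 and 0.0103. Mesothelial genes, described with the cell type markers, were also higher in the aorta. Of these 11 genes, 8 (Cst9, Calcb, Apela, Slurp1, Clic3, Pard6b, Fgfbp1 and Krt7) had their highest and lowest aorta values on the same arrays as the mean of the mesothelial markers, replicates 1 and 3: Calcb was at 10.05 and 7.55 there, and Krt7 at 10.06 and 8.09.

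Transcription factors of the outflow tract and neural crest split between the vessels: of 42 measured, 8 were higher in the ductus and 5 in the aorta (13 and 11 adjusted over the list alone). Beside Tfap2b and Foxf1, Sox9 was 3.84-fold higher in the ductus (adjusted p = 0.000160) and Dlx2 3.21-fold (adjusted p = 0.00111). The cardiac factor Tbx20, chosen after its values were seen, was 4.61-fold higher in the aorta (8.84 ± 0.367 against 6.63 ± 0.468; adjusted p = 0.00131). Prdm6, a smooth muscle regulator, showed a log2 difference of 0.17 ± 0.168 (adjusted p = 0.694). Camera did not call this list (adjusted p = 0.123), and its median, -0.01, and mean, 0.25, differed in sign.

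Hox genes, which set position along the body axis, were in part higher in the ductus. Of 26 measured, 10 were higher in the ductus and 0 in the aorta (14 and 0 adjusted over the list alone). Hoxb5 rose from 4.24 ± 0.386 in the aorta to 7.95 ± 0.468 in the ductus, Hoxd3 was 5.11-fold (adjusted p = 0.00219), Hoxa5 3.61-fold (adjusted p = 0.000388) and Hoxb3 2.49-fold higher (adjusted p = 0.000414). Camera called the list higher in the ductus (adjusted p = 4.70e-09), and this was the 1 list of 36 that kept its call with an estimated correlation (adjusted p = 0.0153).

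Contractile smooth muscle genes were higher in the ductus in part. Of 24 measured, 6 rose and 0 fell (10 and 0 adjusted over the list alone). The enteric-type smooth muscle actin Actg2 was 7.82-fold higher (10.94 ± 0.242 against 7.97 ± 0.408; adjusted p = 8.28e-05) and the intermediate filament gene Des 5.05-fold (adjusted p = 0.000889). Of 2 Des probe sets, 1 went in this direction. The smooth muscle myosin heavy chain Myh11 was 2.00-fold higher (adjusted p = 0.00623), the calponin Cnn1 2.66-fold (adjusted p = 0.0273) and the myosin light chain kinase Mylk 1.57-fold (adjusted p = 0.0109). The main vascular actin Acta2 differed by log2 0.21 ± 0.124, which did not pass (adjusted p = 0.464). Camera called the list higher in the ductus (adjusted p = 1.93e-09), but the call was lost with an estimated correlation (adjusted p = 0.368). The call of Cnn1 was lost on leaving out any of 5 arrays (aorta replicates 1 and 4, and ductus replicates 1, 3 and 4), with adjusted p up to 0.0794. With the skeletal muscle markers, which include Des, as a covariate chosen after seeing the data, Cnn1 (adjusted p = 0.125) and Mylk (0.0546) did not pass.

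Both parts of the vascular ATP-sensitive potassium channel were higher in the ductus. Kcnj8, the pore, was at 9.02 ± 0.238 in the ductus and 5.86 ± 0.327 in the aorta (8.97-fold, adjusted p = 2.50e-05), and Abcc9, the sulfonylurea receptor, was 2.60-fold higher (adjusted p = 0.00550). With the probe set of largest interquartile range, the Abcc9 difference was log2 1.14 and not called (adjusted p = 0.156). Of 25 potassium channel genes, 4 rose and 2 fell (6 and 3 adjusted over the list alone). The 2-pore channel Kcnk1 was 2.98-fold higher (adjusted p = 0.00190), whereas Kcnab1 was 4.81-fold (adjusted p = 0.000171) and Kcnd3 2.26-fold higher in the aorta (adjusted p = 0.00219). The oxygen-sensitive channel Kcna5 differed by log2 -0.48 ± 0.31 (adjusted p = 0.515), and passed without ductus replicate 3 (log2 -0.82, adjusted p = 0.0386) and with the skeletal muscle covariate (log2 -1.02, adjusted p = 0.0239). Of 26 calcium channel and store genes, Cacna2d3 alone was called, and the L-type channel Cacna1c differed by log2 0.61 ± 0.221 (adjusted p = 0.198). Camera did not call the potassium (adjusted p = 0.619) or calcium list (adjusted p = 0.548). The potassium list had a median of -0.18 and a mean of 0.14.

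In the prostaglandin pathway, 1 receptor gene was higher in the ductus, and an enzyme and a transporter that clear prostaglandins were higher in the aorta. Ptger4, the EP4 receptor for prostaglandin E, was 1.84-fold higher in the ductus (12.08 ± 0.065 against 11.20 ± 0.283; adjusted p = 0.00907). Hpgd, the enzyme that inactivates prostaglandins, was 2.69-fold (adjusted p = 0.0130) and the prostaglandin transporter Slco2a1 2.16-fold higher in the aorta (adjusted p = 0.0123). Over the aorta arrays, Hpgd was highest on replicate 1 (9.80) and lowest on replicate 3 (8.58), as was the mesothelial marker mean (9.19 and 7.79). Slco2a1 was lowest on replicate 3 too (7.155) but highest on replicate 2 (7.71). Which cells express these genes was not tested. With the skeletal muscle markers as a covariate, chosen after seeing the data, Ptger4 (log2 0.82, adjusted p = 0.055) and Hpgd (log2 -1.40, adjusted p = 0.0619) did not pass. Ptgs2, the inducible cyclooxygenase, differed by log2 1.05 ± 0.399 and did not pass (adjusted p = 0.224). With the thymus markers as such a covariate it passed (log2 1.41, adjusted p = 0.0182). Of 18 genes, 1 rose and 2 fell (3 and 3 adjusted over the list alone), and camera did not call the list (adjusted p = 0.619; median -0.06, mean -0.03, test direction up).

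Genes of cyclic nucleotide signalling went both ways: of 29, 3 rose and 2 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.815). The cyclic AMP phosphodiesterases Pde4d and Pde4b were 3.10-fold (adjusted p = 0.000688) and 1.98-fold higher in the ductus (adjusted p = 0.00804). Of 6 Pde4b probe sets, 3 went in this direction and 2 were called, and the mean over probe sets did not pass (log2 0.32, adjusted p = 0.109). Gucy1a1, a subunit of the nitric oxide receptor guanylate cyclase, was 2.29-fold higher in the aorta (adjusted p = 0.00177). Pde3a differed by log2 0.46 ± 0.253 (adjusted p = 0.419), and the endothelial nitric oxide synthase Nos3 by log2 -0.77 ± 0.215 (adjusted p = 0.0910), which passed without aorta replicate 3 (adjusted p = 0.0177). Among 24 vasoactive receptor and RGS genes, 2 rose and 3 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.619). Rgs5, a regulator of G protein signalling in mural cells, was 1.84-fold higher in the ductus (adjusted p = 0.00226), while Rgs3 was 2.24-fold (adjusted p = 0.00219) and Ramp1, a receptor partner for calcitonin gene-related peptide, 2.99-fold higher in the aorta (adjusted p = 0.00455). Edn1, endothelin 1, differed by log2 0.54 ± 0.141 (adjusted p = 0.0710), and passed without ductus replicate 3 (adjusted p = 0.0456), with array weights (0.0474) and among genes with a mean above log2 6 (0.0454).

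Of 26 oxygen and redox genes, 2 rose and 1 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.431). The cytochrome P450 Cyp1b1 was 3.75-fold (adjusted p = 0.000105) and the oxygen-dependent prolyl hydroxylase Egln3 3.91-fold higher in the ductus (adjusted p = 0.000171).

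The vessels differed in matrix genes, while elastin did not pass the test. Eln was at 12.26 ± 0.040 in the ductus and 12.30 ± 0.106 in the aorta (adjusted p = 0.884). Of 19 elastic fibre genes, 4 rose and 2 fell (6 and 3 adjusted over the list alone): the lysyl oxidase Loxl4 was 3.84-fold (adjusted p = 0.000573) and the fibrillin Fbn2 1.75-fold higher in the ductus (adjusted p = 0.00466), and Fbln1 3.34-fold higher in the aorta (adjusted p = 0.000258). Of 30 collagens and other matrix genes, 6 rose and 1 fell (7 and 6 adjusted over the list alone). Col8a1 was 8.21-fold (adjusted p = 0.000573), Thbs1 3.54-fold (adjusted p = 0.00709) and Col12a1 2.65-fold higher in the ductus (adjusted p = 0.00375). Among 20 hyaluronan and intimal cushion genes, 2 rose and 3 fell (2 and 4 adjusted over the list alone). The hyaluronan synthase Has2 was 2.13-fold higher in the ductus (adjusted p = 0.0166) and the link protein Hapln1 2.04-fold higher in the aorta (adjusted p = 0.00167). Without aorta replicate 2 or ductus replicate 4, Has2 did not pass (adjusted p = 0.0583 and 0.0568), nor with the skeletal muscle covariate (0.0666). Camera called none of these 3 lists (adjusted p of 0.151, 0.322 and 0.655). The median and mean differed in sign in the collagen (-0.004 and 0.20) and hyaluronan lists (0.09 and -0.02).

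Signalling pathways had called members in both directions. In the TGF-beta and BMP list of 29 genes, 3 rose and 2 fell (6 and 4 adjusted over the list alone): Inhba was 2.23-fold higher in the ductus (adjusted p = 0.0101) and the BMP receptor Bmpr1b 2.76-fold higher in the aorta (adjusted p = 0.000445). Of 2 Inhba probe sets 1 went in this direction, and Inhba did not pass as their mean (log2 0.53, adjusted p = 0.0543) or with the skeletal muscle covariate (0.0507). In the Wnt list of 31 genes, 2 rose and 2 fell (6 and 4 adjusted over the list alone), with the agonist Rspo3 4.88-fold higher in the ductus (adjusted p = 0.00108). Of 34 axon guidance genes, 5 rose, among them Slit2 (2.70-fold, adjusted p = 0.000573) and Epha4 (2.05-fold, adjusted p = 0.00286), and 4 fell (6 and 10 adjusted over the list alone). Retinoic acid genes had 1 member higher in each vessel among 17 measured (2 and 1 adjusted over the list alone). Camera called none of these lists (adjusted p of 0.619, 0.798, 0.798 and 0.445). In all 4 lists the median and the mean differed in sign, with medians of -0.065 to -0.001 and means of 0.007 to 0.066.

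Notch pathway genes leaned to the aorta: of 19 measured, 0 rose and 2 fell (0 and 5 adjusted over the list alone). The ligand Dll1 was 2.23-fold higher in the aorta (adjusted p = 0.00827) and Jag2 1.41-fold (adjusted p = 0.0386), the latter passing only with all 8 arrays (adjusted p of up to 0.114 without 1). Jag1 differed by log2 -0.29 ± 0.112 (adjusted p = 0.237) and Notch3 by log2 -0.33 ± 0.116 (adjusted p = 0.180). With the probe set of largest interquartile range, Jag1 was called at log2 -0.82 (adjusted p = 0.0326). Camera called the list higher in the aorta (adjusted p = 0.0286), and not with an estimated correlation (adjusted p = 0.368) or without aorta replicate 2 (adjusted p = 0.0842), aorta replicate 3 (0.0629) or ductus replicate 1 (0.0590).

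Among 26 immediate early genes, 4 were higher in the ductus and 0 in the aorta (7 and 1 adjusted over the list alone). Nr4a3 was 3.50-fold (adjusted p = 0.000467), Nr4a2 2.097-fold (adjusted p = 0.00709) and the matricellular gene Ccn1 1.66-fold higher (adjusted p = 0.00862). Of 6 Nr4a2 probe sets, 4 went in this direction and 1 was called, and the mean over probe sets did not pass (log2 0.305, adjusted p = 0.276). Camera called the list (adjusted p = 0.0138), and not with an estimated correlation (adjusted p = 0.638), without aorta replicate 3 (adjusted p = 0.0926), without the lowest 40% of genes (0.119) or with the mean over probe sets (0.0576). Limma called 0 of 25 cell cycle and 0 of 14 heat shock genes, with 3 and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.0907 and 0.273, fry adjusted p = 0.609 for both). Camera called the cell cycle list higher in the ductus without aorta replicate 4 (adjusted p = 0.0098), ductus replicate 3 (0.0207) or ductus replicate 4 (0.035), and with the skeletal muscle covariate (0.0271).

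**Figure D2:**
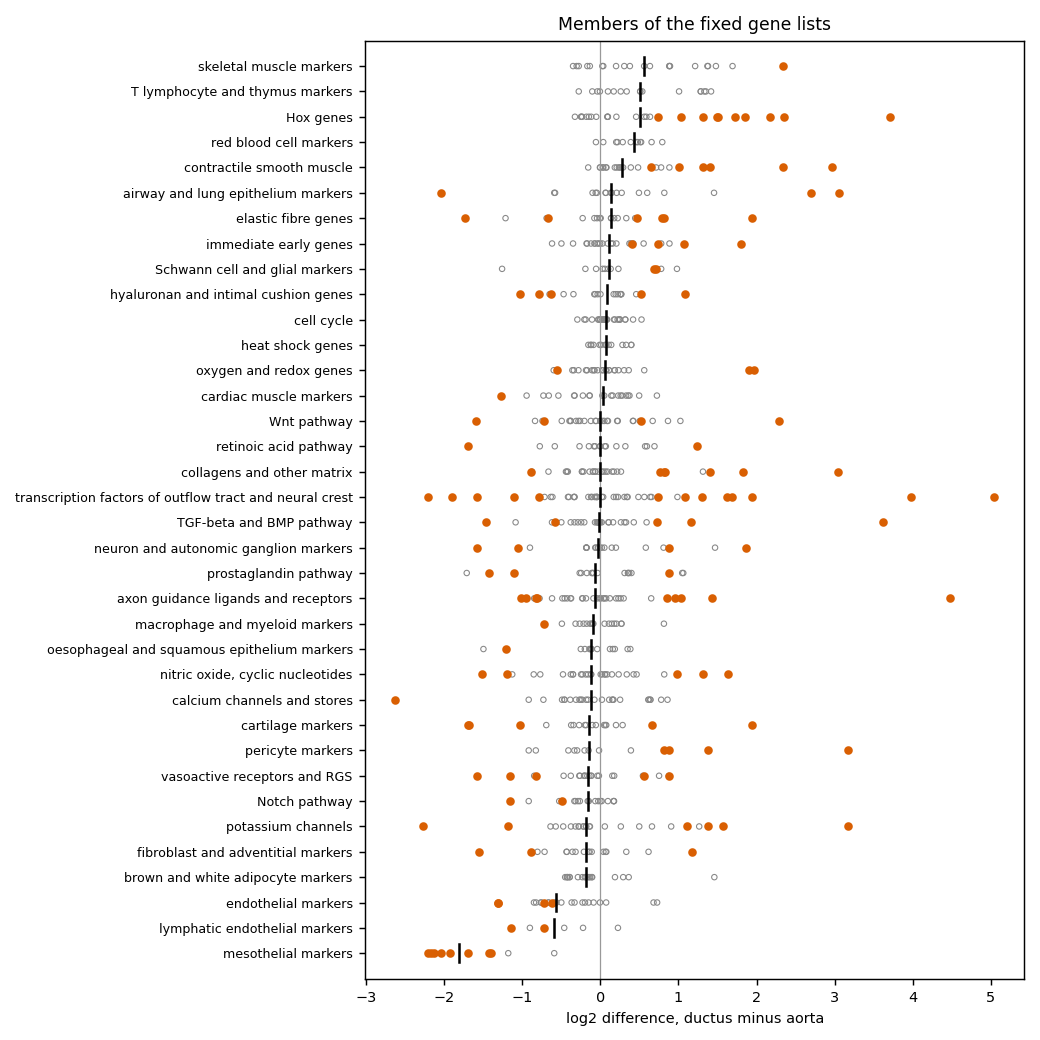
Log2 difference, ductus minus aorta (horizontal axis), of each measured member of the 36 tested gene lists, ordered by list median (black bar). Filled orange points passed an adjusted p under 0.05; the mesothelial list has the lowest median, -1.81, with 8 of 10 members called.

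Markers of other cell types also differed. All 10 measured mesothelial genes were lower in the ductus and 8 of them passed (9 adjusted over the list alone), with a median log2 difference of -1.81. The mucin Muc16 was 4.37-fold (adjusted p = 0.00155), Krt19 4.11-fold (adjusted p = 0.00219) and the uroplakin Upk1b 2.69-fold higher in the aorta (adjusted p = 0.00416). Of 23 endothelial genes, 0 rose and 4 fell (1 and 13 adjusted over the list alone; median -0.56). The tight junction gene Cldn5 was 2.48-fold (adjusted p = 0.0154, and 0.0522 without ductus replicate 4) and the angiopoietin receptor Tek 1.65-fold higher in the aorta (adjusted p = 0.00907). Camera called the mesothelial (adjusted p = 2.58e-11) and endothelial lists (adjusted p = 8.03e-07) higher in the aorta, and neither with an estimated correlation (adjusted p = 0.368 for both). Of 6 lymphatic endothelial genes, 2 fell, among them Pdpn, also made by mesothelium (2.20-fold, adjusted p = 0.0135). Camera did not call this list (adjusted p = 0.0646), but called it higher in the aorta with cyclic loess (0.040), with the probe set of largest interquartile range (0.0495), with the trended robust prior (0.0381) and without aorta replicate 3 (0.000866), ductus replicate 2 (0.0499) or ductus replicate 3 (0.0382). It also did with the skeletal muscle (0.0402) or adipocyte markers (0.0227) as covariates chosen after seeing the data.

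Camera called none of the lists of mural, nerve, cartilage and fibroblast markers, which held 2 to 5 called genes each. Of 13 pericyte genes, 4 rose and 0 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.322), namely Kcnj8, Rgs5, Abcc9 and Mcam (1.76-fold, adjusted p = 0.0122). Their median, -0.15, and mean, 0.27, differed in sign. Of 21 neuron and ganglion genes, 2 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.619). Syt1, a synaptic vesicle gene, was 3.65-fold higher in the ductus (adjusted p = 0.000575), while Hand2 was 2.99-fold (adjusted p = 0.00575) and Gap43 2.08-fold higher in the aorta (adjusted p = 0.0116). Of 12 Schwann cell and glial genes, 2 rose, including Cdh19 (adjusted p = 0.01003; camera adjusted p = 0.115), whose aorta mean, 2.58, was below every first quartile, so no fold is given. Of 18 cartilage genes, 2 rose and 3 fell, with aggrecan (Acan) 3.23-fold (adjusted p = 0.00447) and Cytl1 3.21-fold higher in the aorta (adjusted p = 0.000604; camera adjusted p = 0.322). Fibroblast and adventitial genes had 1 rise and 2 falls among 18, with Igfbp6 2.93-fold higher in the aorta (adjusted p = 0.0118; camera adjusted p = 0.115, and 0.0289 with cyclic loess).

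Genes known from neighbouring tissues were followed as markers. Of 18 airway and lung epithelium genes, Scgb1a1 (8.30-fold, adjusted p = 0.000992) and Scgb3a2 (6.47-fold, adjusted p = 0.0266) rose in the ductus and Krt19 fell. Camera did not call this list (adjusted p = 0.205). The aorta mean of Scgb1a1, 3.31, lay little above the first quartiles, so its fold can be compressed. Scgb3a2 did not pass without aorta replicates 1, 2 or 3 or ductus replicates 1, 2 or 4, each left out alone (adjusted p of up to 0.0757). The surfactant gene Sftpc, chosen after its values were seen, did not pass (6.38 ± 2.42 against 4.92 ± 1.64; adjusted p = 0.615). None of 17 thymus genes was called by limma, and 0 had an unadjusted p under 0.05: Cd8a was at 7.41 ± 2.06 in the ductus and 6.00 ± 2.43 in the aorta, and Rag1 at 6.18 ± 1.66 and 4.82 ± 1.37 (adjusted p = 0.662 and 0.504; camera adjusted p = 0.115). Camera called the thymus list without aorta replicate 4 (adjusted p = 0.00437) or ductus replicate 4 (0.00594). Skeletal muscle genes were called by camera (adjusted p = 0.0175), though Des was the 1 member that passed of 21. Their mean was 1.45 (log2) above the mean of the 8 arrays on ductus replicate 3. The call was lost without that array (adjusted p = 0.0634), without aorta replicate 2 (0.109) or aorta replicate 3 (0.0527), and with an estimated correlation (adjusted p = 0.743). Camera also called 12 red blood cell genes higher in the ductus (adjusted p = 0.0138) with 0 members passing limma's test and 1 at an unadjusted p under 0.05. That call was lost with an estimated correlation (adjusted p = 0.743) and without aorta replicate 2 (0.167), aorta replicate 3 (0.0892) or ductus replicate 1 (0.0966).

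**Figure D3:**
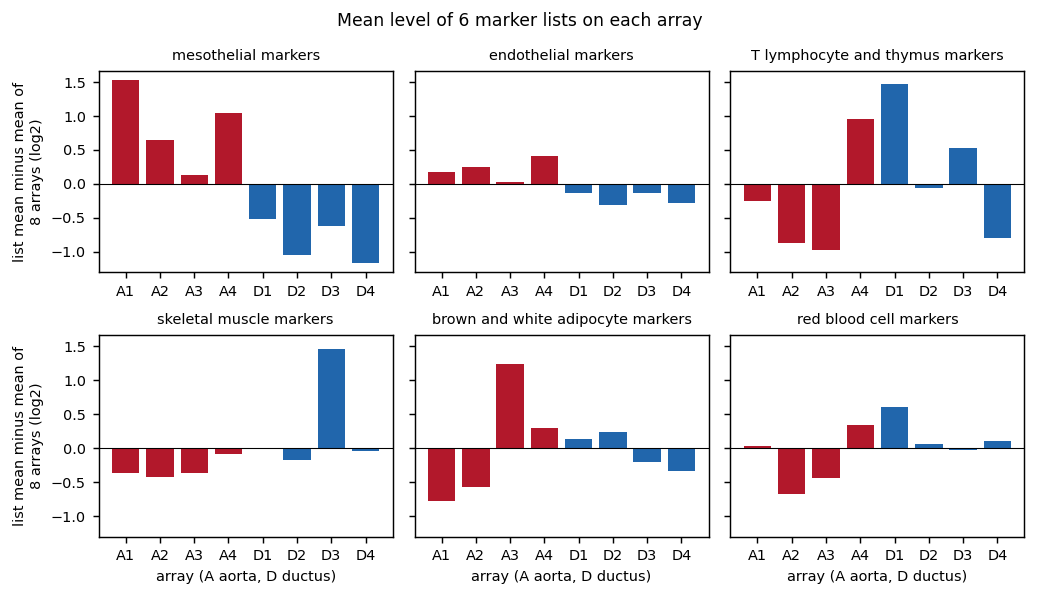
Mean log2 level of 6 marker lists on each array, minus the mean of the 8 arrays (vertical axes, log2), for aorta (red, A1 to A4) and ductus (blue, D1 to D4). Mesothelial genes were above the mean on every aorta array (0.14 to 1.53), whereas skeletal muscle genes stood out on ductus replicate 3 (1.45) and adipocyte genes on aorta replicate 3 (1.24).

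Macrophage, cardiac muscle and squamous epithelium markers had 1 member higher in the aorta each (of 18, 22 and 14), and adipocyte markers had 0 of 19 called by limma (2 at an unadjusted p under 0.05). Limma called 0 of the 4 sex-linked genes. Camera called none of the macrophage (adjusted p = 0.916), cardiac, squamous and adipocyte lists (adjusted p = 0.619 each). Adjusted over the list alone, genes higher in the ductus and in the aorta numbered 1 and 2 for calcium channels, 2 and 1 for Schwann cells, 2 and 5 for cartilage, 3 and 7 for fibroblasts, 2 and 1 for airway, 2 and 0 for skeletal muscle, 0 and 2 each for lymphatic, macrophage and squamous, and 0 and 1 for cardiac markers. The median and mean also differed in sign for neuron (-0.03 and 0.08) and cardiac markers (0.04 and -0.09). Among the 100 genes named, 62 had several probe sets, which all went in the same direction for 50. In the other 12 genes no probe set of opposite direction was called. Camera called 8 of the 36 lists in all, and in 13 of the 35 splits of the 8 arrays into 4 and 4 it called as many. Limma's count rests on pools of pups, each pool from a single pregnant female, so that differences between single fetuses were not measured.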

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

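The tests of lung tissue, airway epithelium and smooth muscle share were chosen only after their results were seen. An array was set apart where its gap to the nearest other array of its tissue exceeded the critical share of the range for 4 values. This was so in 10 of 200 groups of values, where chance gives about 10. Tbx20, Sftpc, Myh3 and Ucp1, chosen after their values were seen, each gave 1 of the 10. The count is therefore not a fair comparison with chance.

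Some of the values set apart were of genes known from other tissues, and Myh3, Ucp1 and Sftpc were picked after their values were seen. Myh3, the embryonic skeletal muscle myosin, was at 7.77 on ductus replicate 3 and at 3.00 to 3.67 on the other ductus arrays. Ucp1, the brown fat uncoupling protein, was at 6.07 on aorta replicate 3 and at 3.11 to 3.32 on the others. Sftpc was at 7.38 on aorta replicate 4 against 3.92 to 4.25, and Scgb1a1 at 3.96 on the same array against 3.05 to 3.13. Clic3 was low on aorta replicate 3 (5.05 against 6.50 to 6.79), and Fgfbp1 on ductus replicate 4 (5.15 against 6.03 to 6.16). Tbx20 was low on ductus replicate 3 (5.93 against 6.83 to 6.93), where Kcnj8 was high (9.38 against 8.87 to 8.95). Pdpn was high on aorta replicate 1 (11.40 against 10.62 to 10.68) and Epha4 on aorta replicate 4 (8.30 against 7.87 to 7.94).

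The airway secretory genes Cxcl15, Scgb1a1 and Scgb3a2 were higher in the ductus. Surfactant-bearing lung tissue as the whole source was examined with the mean of the surfactant genes as a covariate. The mean of the secretory genes was then still higher in the ductus by log2 3.43 (95% interval 2.47 to 4.40), against 3.63 without it. The secretory genes were picked after they were seen to be higher in the ductus, which favours a positive difference. The surfactant mean was also low on some arrays, such as 3.05 on aorta replicate 2 and 3.38 on ductus replicate 2. The covariate could take up little there, so the interval alone does not decide. Sftpc was at 4.25 on ductus replicate 2, where Cxcl15 was at 11.08, and at 7.38 on aorta replicate 4, where Cxcl15 was at 6.70. Airway epithelium without surfactant cannot be told apart from expression in the vessel: the median difference of Epcam, Cdh1, Foxj1, Foxa1 and Foxa2 was 0.066, but 4 of these 5 genes lay below the median of all values. A difference between the tissues themselves stays open and was not tested.

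Mesothelial genes were higher in the aorta, with Krt19 at 9.45 there and 7.41 in the ductus; 3 of the 10 genes stand in another fixed list too. Another scaling of the arrays left the median of the list at -1.80 or further from 0, more than the SD over members. The deposited RMA values had array medians that were already close, so these scalings could change little. This test therefore cannot decide on scaling. Within tissues the members deviated together, with a mean pairwise correlation of 0.875 against 0.187 at the 95th percentile of 10000 random lists of genes above the median level. A larger share of mesothelial cells in the aorta pools would go with this. The random lists were not marker lists, however, so that share cannot be told apart from a difference in these cells. Whether such cells belong to the vessel's outer surface or came with the dissection was not tested.

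Of 24 contractile genes, 6 were higher in the ductus, and camera's call of the list was lost with an estimated correlation (adjusted p = 0.368). Under other scalings the mean of the list was at least 0.58, but these could change little in RMA values with close array medians, so scaling was not decided. A larger share of smooth muscle cells in the ductus pools cannot be told apart from a difference in these cells. The members' differences ran from -0.16 to 2.97 (Cochran's Q over its degrees of freedom 15.5, limit 1.53), but this excludes nothing: 12 members had means in the top 5% of values, where differences can be compressed, and others, such as Srf, are made by many cell types. A difference between the tissues themselves stays open and was not tested.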

How the results depend on the processing

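The thymus, skeletal muscle and adipocyte covariates were chosen after seeing the data. The 702 called genes became 403 (208 higher in the ductus, 195 in the aorta) with a replicate block, 304 (170, 134) at an adjusted p under 0.01, 135 (90, 45) with treat against 1.5-fold and 340 (198, 142) with an ordinary model without the shared prior. Over all probe sets the count was 1108, with 567 higher in the ductus, since more rows were tested. The 11 called anchor genes became 7 at an adjusted p under 0.01, 3 with treat and 6 with the ordinary model. With the skeletal muscle covariate, which takes up a degree of freedom and follows ductus replicate 3, 443 genes were called (204, 239). The thymus and adipocyte covariates also take up a degree of freedom each, and gave 747 and 712 genes. Neither the cause of the fall to 443 nor that of the other changes was tested. Equal array medians, cyclic loess, both filters, both other rules for 1 value per gene, the trended robust prior and array weights kept the gene counts within 1.5 times. Leaving out 1 array at a time gave 443 to 705 genes, 233 to 289 higher in the ductus and 201 to 419 in the aorta, 5 to 10 lists and 9 to 12 anchor genes.

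Equal replicate numbers did not deviate together (correlations of -0.23 to -0.07), and 0 of the 8 arrays was matched best by its own number. The labels do not say whether equal numbers mark the same litter, so the numbers served as pairs only in the replicate block. No fit with another matching was made. The 8 called lists became 5 without the lowest 40% of genes, 5 with a mean above log2 6, 1 with an estimated correlation and 5 with the thymus covariate. Fry called 7, losing the immediate early (adjusted p = 0.0932), red blood cell and skeletal muscle lists (0.478 each) and gaining the transcription factor (8.89e-05) and Schwann cell lists (0.022). The Notch and red blood cell calls were lost with either filter and with the thymus covariate, which also ended the skeletal muscle call (0.0508). The contractile, Hox, endothelial and mesothelial calls held without each array in turn. Of the 100 named genes, 12 lost their call with the replicate block, among them Ptger4 (adjusted p = 0.05003), Slco2a1 (0.0792) and Tek (0.0583), 15 at an adjusted p under 0.01, 38 with treat and 26 with the ordinary model, among them Pou4f1 (0.0501), Calcb (0.0562), Clic3 (0.0523), Krt7 (0.0720) and Abcc9 (0.0521). The mean over probe sets ended 4 calls and equal array medians 0. With the skeletal muscle covariate, 9 did: Ptger4, Hpgd, Cnn1, Has2, Mylk, Jag2, Inhba, Gap43 and Mcam. Ucp1, not called, had log2 differences of -0.67 to 0.32 with 1 array left out, the positive value without aorta replicate 3, and with the skeletal muscle covariate Sftpc (-0.51) and Myh3 (-0.054) changed sign.

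Only the real split of the 8 arrays called as many as 702 genes, 1 of 35 splits, and the highest other split called 5. With 35 splits, 1 in 35 is the smallest possible share, so this test alone cannot exclude chance. The other splits mix the tissues within each group, which can itself lower their counts. For the 8 lists the real split did not stand out: 13 of 35 splits called as many by camera, up to 12. The reason was not tested. The p of the contractile, Hox, endothelial and mesothelial lists was smallest in the real split, as was that of the uncalled transcription factor and Schwann cell lists. For the contractile list another split came close (1.74e-10 against 1.07e-10), as for the endothelial list (3.46e-07 against 8.92e-08).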

Other observations

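The test of a shared order of litters was chosen only after its result was seen. Probe sets without a single gene name, 10092 in all, held a further 110 higher in the ductus and 64 in the aorta in a fit of all probe sets.

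Within tissues, deviations of the arrays from their tissue's mean pointed to a matching other than the replicate numbers. Aorta replicates 1, 2, 3 and 4 correlated best with ductus replicates 2, 3, 4 and 1, with a mean correlation of 0.278 over 17516 autosomal genes, against 0.219 for the next of 24 matchings and -0.16 for equal numbers. A candidate explanation is that arrays came from the same litters in another order. Sex-linked genes, whose level follows the share of males in a pool, placed this matching at rank 2 of 24 (exact p = 0.083, with 1 in 24 the smallest possible share), which leaves the explanation open. Apart from the replicate block, the p-values and splits given treat the arrays as unpaired, and no fit with this matching was made.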
